A study of Mus musculus with 4 samples.

How the data were processed

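Single-cell 3′ RNA libraries (10x v3.1) were made from back skin of BALB/c mice. Treated mice received 25 µg DMBA once and, from 1 week later, 5 µg TPA weekly 3 times; cells were taken 3 weeks after treatment from 3 mice pooled per genotype, sorted into CD45+ and CD45- fractions and mixed 1:1. Naive skin gave 1 CD45+ and 1 CD45- library, each labelled as a 1:1 pool of WT and Cd226-/- cells. The deposited matrices hold raw UMI counts per feature and cell barcode, with 31053 genes (31017 unique symbols) and 2 antibody tags (CD45 and DNAM-1). The counts were made by the authors with Cell Ranger 3.1.0 against mm10, per the submitters' processing notes, and hold called cells only. Empty droplets are not given in the sources used here, so free RNA could be measured only from the cells themselves. Coordinates are those of GRCm38 with GENCODE vM21.

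WT, Cd226-/-, naive CD45- and naive CD45+ libraries held 8527, 7991, 11875 and 5913 barcodes and 72606822, 71245703, 81406730 and 42043869 gene UMIs. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, and doublets called by Scrublet (through scanpy 1.11.5, expected rate 0.06, automatic threshold) were left out. Fewer than 500 genes were seen in 931, 933, 358 and 1119 barcodes and over 10% mitochondrial UMIs in 1128, 1110, 506 and 2307; doublets were 190, 161, 603 and 19. In the naive CD45+ library only 0.54% were called, just above the 0.5% below which the highest 5% of scores would have been removed instead. The kept cells numbered 7022, 6521, 10597 and 3494, with median genes of 2583.5, 2645, 2075 and 2519.5. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes (ranked over libraries), 30 principal components, a shared-neighbour graph of 15 neighbours and Leiden clustering at resolution 1.0 gave 32 clusters over all libraries (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9; figures with matplotlib 3.10.9). No batch correction was used, since group and library coincide.

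Clusters were named by fixed marker genes as "-like" classes. A cluster was called immune when at least 40% of its cells had a Ptprc UMI, and it took the name with the highest marker score if that was at least 3 and at least 3 markers were detected in 10% of the cells. The score is the mean log2 level of the markers over their lower quartile across clusters. Best lymphoid, myeloid and non-immune scores of at least 2.8 and less than 1.1 apart left a cluster unnamed as mixed, as did a neutrophil score of at least 3 with a monocyte score of at least 4.5. These thresholds were set after the clusters had been seen. Unnamed cells were 8.30%, 8.80% and 2.71% of immune cells in WT, Cd226-/- and naive CD45+ skin, and 9.65%, 9.88% and 0.114% of non-immune cells in WT, Cd226-/- and naive CD45- skin. Mixed clusters and lymphocytes were clustered again; lymphocytes gave 11 sub-clusters, whose subset names were not reliable, so that αβ and γδ T cells, NK cells and innate lymphoid cells stay 1 class where T lymphocytes had been planned. Many unnamed immune cells hold T-cell transcripts, so 4 genes were later also read over all immune cells.

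For each class with at least 100 cells in both libraries, UMIs were summed over cells and divided by the class total. A ratio has the exact conditional binomial 95% interval, a level the exact Poisson interval and a share the exact binomial interval. These cover counting error only: with 1 library per group no test, p-value or count of differing genes is given. A gene with no UMI in one library was set to 3 counts there, over the whole class, and is written "at least". 24 gene lists and the choices above, apart from those named as later ones, were fixed before the data were examined, and 23 lists had a median in at least 1 class; which lists are described in which class was settled after a first look at all of them. A list's median covers members with at least 50 UMIs over both libraries and is placed among 10000 random lists of the same size, drawn from 10 bins of like expression. Keratinocytes, the class for which epidermal lists had been planned, were too few in Cd226-/- and naive skin, so those lists are not reported for keratinocytes; 1 of them, keratinocyte wound genes, is given in Langerhans cells as a sign of RNA from other cells. Since these intervals treat UMIs of 1 cell as separate, each ratio was also taken with the richest cell, the one with most UMIs of the gene, left out of each library, an alternative chosen after seeing the data. Named genes are, per comparison and class, the 3 highest and 3 lowest by the interval bound nearest to equality, among genes with at least 50 UMIs, a 1.5-fold ratio under both scalings and, where higher, at least 0.1 times the level of the class highest for the gene. Mitochondrial, ribosomal, hemoglobin, variable-receptor, sex-linked, Gm and Rik genes were left out. Where a planned class was too small, the next most numerous took its place. Cd226, its receptor and ligand family, Ifng and examples of each list were named besides. Counting unnamed cells in the last condition, a reading added later, replaces 4 of the 90 genes: Sostdc1, Igfbp2, Sfrp2 and Inhba.

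Shares of lymphocytes with a UMI were taken after thinning every cell to 1000 UMIs, in 1 draw, with the median of 100 draws added later. Alternatives were a looser cell filter (200 genes, 20% mitochondrial UMIs), doublets kept, Leiden resolution 2.0, each library clustered on its own, scaling by trimmed means (edgeR 4.0.16, R 4.3.3), cells weighted equally, gene minima of 1 and 200 UMIs, and no thinning or thinning to 2000 UMIs. Monocytes and macrophages apart were added later. Free RNA was weighed by subtracting a fibroblast-marker part from each class and, added later, a T-cell-marker part from phagocytes. Sex-linked expression was male in all libraries. The ratio method was tested on simulated data with 200 altered genes per comparison and no spread between cells or mice. For Cd226-/- over WT phagocytes (9477 genes) the interval held the true ratio for 95.8% of genes and excluded equality for 96.9% of 98 genes altered 2-fold, all 99 altered 4-fold and 4.23% of unaltered genes; for lymphocytes (6850 genes) the values were 95.8%, 95%, all and 4.29%, and for WT over naive fibroblasts (12843 genes) 95.5%, 98.0%, all and 4.56%. A list lowered 2-fold came out at percentile 0 in each, and an unaltered list at 43.0, 16.6 and 22.2.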

Results

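Back skin of BALB/c mice was profiled in 4 single-cell RNA libraries to ask what the activating receptor CD226 (DNAM-1) does for inflammation and the interferon-γ (IFN-γ) response in skin under chemical carcinogenesis. 1 library held WT and 1 held Cd226-/- cells after 25 µg of the mutagen DMBA and 3 weekly applications of 5 µg of the tumor promoter TPA, each pooled from 3 mice. The other 2 held CD45+ and CD45- cells of untreated (naive) skin, and both are labelled as pools of WT and Cd226-/- cells. After filtering, 7022 WT, 6521 Cd226-/-, 10597 naive CD45- and 3494 naive CD45+ cells remained, with medians of 8340.0, 9073, 6552 and 8937 UMIs per cell. With 1 library per group there is no replicate check and no test between groups: each interval is an exact 95% interval of counting error alone, and every difference below is a difference between these libraries.

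Cd226 itself was read first in every library. Lymphocyte-like cells held 101 Cd226 UMIs in WT, 47 in Cd226-/- and 16 in naive CD45+ skin, and 0 in the 5 lymphocyte-like cells of naive CD45- skin. Per 1000000 UMIs this is 52.9 (43.1–64.2), 19.3 (14.2–25.7) and 8.69 (4.97–14.1). A Cd226 UMI was seen in 18.8%, 5.46% and 4.41% of these cells at median depths of 3555, 3432 and 5879.5 UMIs, against 0.0491%, 0.0357% and 0% of fibroblast-like cells at 10138, 12660.0 and 15404 UMIs. With every cell thinned to 1000 UMIs the shares were 5.53% (3.54–8.18) in WT and 1.32% (0.574–2.59) in Cd226-/- (medians of 100 draws 4.81% and 1.82%). Within 1 sub-cluster of lymphocytes, sub-cluster 0, medians of 100 draws were 5.97% (2.61–11.4) in WT and 5.10% (1.68–11.5) in Cd226-/-, so the lower share over all lymphocytes is not told apart from their mix, given below. The 3′ tag of a partly deleted gene can still be read, so the 47 UMIs left in Cd226-/- neither check nor contradict the label. The antibody tag for DNAM-1 protein separated the libraries more clearly: its median was 43 counts in lymphocyte-like and 16 in fibroblast-like cells of WT, and 2 in both classes of Cd226-/-. In naive CD45+ skin it was 10 in both, and in naive CD45- skin 113 and 106, where no signal stood above background.

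Cells were sorted into classes by marker genes, so every class name here stands for a "-like" class. Immune classes made up 95.1% (94.3–95.8) of the naive CD45+ library and 1.04% (0.854–1.25) of the naive CD45- library. In the treated libraries, whose sorted fractions are labelled as mixed 1:1, the share was 27.3% in WT and 50.01% in Cd226-/-. The WT share does not match this, and after mixing neither is read as a property of the skin. Class shares below are taken within the immune or the non-immune compartment, of which 8.30% and 9.65% stayed unnamed in WT and 8.80% and 9.88% in Cd226-/-.

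Which cells differed between the treated genotypes? Monocytes were 33.8% (32.2–35.4) of immune cells in Cd226-/- and 22.8% (21.0–24.8) in WT, whereas macrophages were 12.6% (11.5–13.8) and 19.2% (17.4–21.0). Lymphocytes were 18.5% (17.2–19.9) and 21.7% (19.9–23.6), dendritic cells 6.19% (5.39–7.08) and 4.54% (3.66–5.57), and neutrophils 8.10% (7.18–9.09) and 8.25% (7.06–9.57). Langerhans cells were 10.4% (9.34–11.5) and 14.1% (12.6–15.7), a difference that was gone when each library was clustered on its own (9.97% and 10%). Neutrophil shares differed under that clustering instead (8.33% and 11.1%). Mast cells or basophils were 1.60% (1.19–2.09) and 1.097% (0.680–1.67). Among non-immune cells, keratinocytes were 0.736% (0.472–1.09) in Cd226-/- and 4.03% (3.51–4.61) in WT, and melanocytes 0.368% (0.190–0.642) and 1.63% (1.30–2.01). Endothelial cells were 1.72% (1.30–2.23) and 3.35% (2.87–3.88), lymphatic endothelial cells 1.23% (0.878–1.67) and 1.61% (1.28–1.99), and fibroblasts 86.0% (84.7–87.2) and 79.7% (78.6–80.8). Losses during dissociation were not measured, and 1 library per genotype cannot separate them from genotype.

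How did the mix of cells in treated skin differ from naive skin? Of immune cells in naive CD45+ skin 58.5% (56.8–60.2) were macrophages and 15.9% (14.7–17.2) neutrophils, with few monocytes (4.82%, 4.11–5.60), lymphocytes (8.19%, 7.28–9.17) and Langerhans cells (1.11%, 0.785–1.53). Both treated libraries had lower macrophage and neutrophil shares and higher monocyte, lymphocyte and Langerhans shares than naive skin. Dendritic cells were 8.19% (7.28–9.17) and mast cells or basophils 0.542% (0.321–0.855) in naive skin. Naive CD45- skin was 97.0% (96.7–97.3) fibroblasts, with 0.572% (0.437–0.736) keratinocytes, 1.37% (1.16–1.62) endothelial cells, 0.563% (0.429–0.725) lymphatic endothelial cells and 0.153% (0.0870–0.248) melanocytes. At a finer clustering the naive monocyte share was 15.6% and the naive macrophage share 46.0%, with the same directions.

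**Figure D1:**
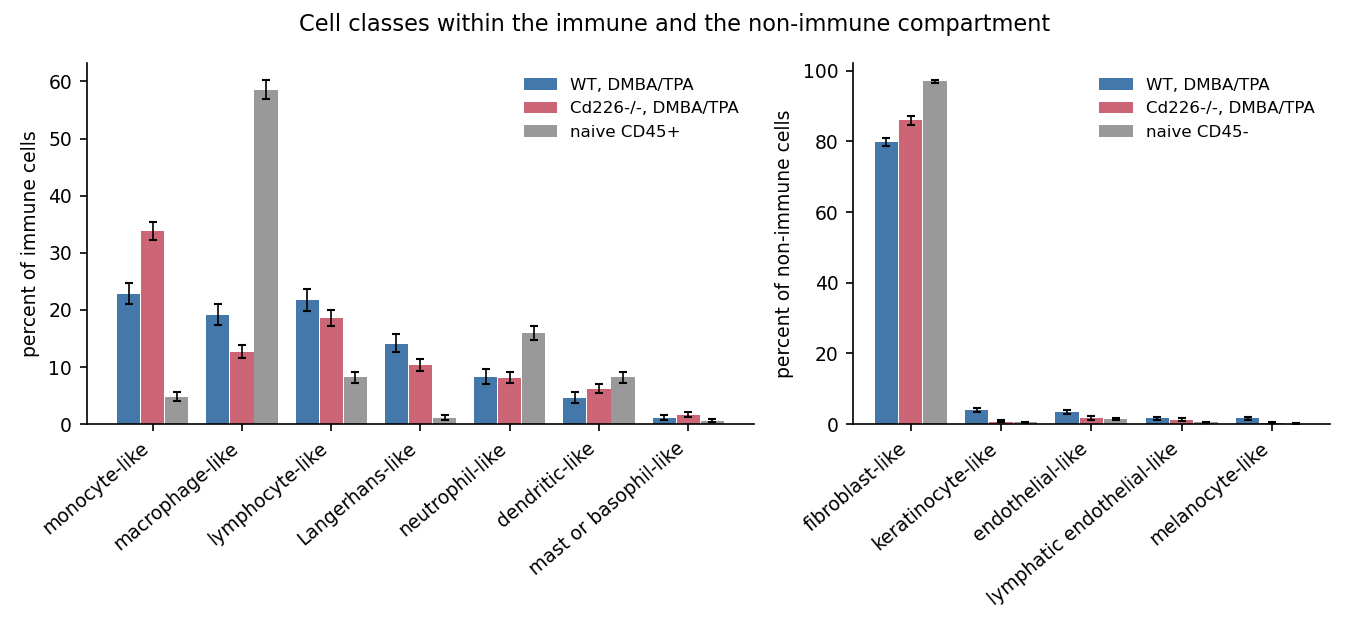
Percent of immune cells (left) and of non-immune cells (right) in each class, for the WT and Cd226-/- DMBA/TPA libraries and the matching naive library; bars are shares, lines exact 95% binomial intervals. Monocytes were 33.8% of immune cells in Cd226-/- and 22.8% in WT, and macrophages 58.5% in naive skin.

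How did lymphocytes differ between the genotypes after DMBA/TPA? From here on a pair of values gives UMIs per 1000000 UMIs of the class (CPM), Cd226-/- before WT, followed by the fold and its interval. The IFN-γ gene Ifng (106 against 332, 3.14-fold, 2.71–3.65) was lower in Cd226-/-. A list is given by its median log2 ratio, with members of 0 counts set to 3, and by the percentile of that median among 10000 random lists of like expression, as a description of these libraries. The genes of granzymes A and K, Gzma (729 against 1877, 2.58-fold, 2.43–2.73) and Gzmk (5.76 against 30.9, 5.36-fold, 2.96–10.4), and the chemokine Ccl5 (354 against 892, 2.52-fold, 2.32–2.74) were lower too, as was the T-cell coreceptor chain Cd8b1 (105 against 224, 2.13-fold, 1.82–2.49). 14 of 22 genes of the cytotoxic and type 1 list were lower (median log2 ratio −0.15, percentile 0.570), but not all: Gzmb was level over the class at 883 against 898, and Gzmf (55.6 against 20.9, 2.65-fold, 1.85–3.88) was higher. Type 2 genes were higher instead, with Il5 (44.0 against 3.66, 12.0-fold, 5.64–30.6), Il13 (333 against 91.1, 3.66-fold, 3.105–4.34) and Areg (3176 against 1849, 1.72-fold, 1.65–1.79) among 6 of 7 higher genes of that list (median log2 ratio 0.78, percentile 99.99, smaller when each library was clustered on its own). Of the type 17 list 12 of 13 genes were higher (median log2 ratio 0.47, percentile 100), such as Il17a (8960.1 against 6886, 1.30-fold, 1.27–1.33) and Cd163l1 (422 against 222, 1.90-fold, 1.69–2.13), of which Cd163l1 turned with each library clustered on its own. The γδ T-cell receptor constant gene Trdc (1356 against 724, 1.87-fold, 1.76–1.996) was higher too. Il22 was the exception: 4032 against 4807. In each class genes past the 1.5-fold and level filters were ranked by the interval bound nearest to equality. In lymphocytes the first were Klk4 (28.8 against 0, at least 18.4-fold), Il5 and Slc17a6 (34.6 against 5.23, 6.61-fold, 3.42–14.3) upward and Cxcl9 (0 against 31.9, at least 25.9-fold) and Ifitm1 (469 against 1843, 3.93-fold, 3.67–4.203) with Gzmk downward. 1 cell held 54 of 70 Klk4 UMIs in Cd226-/-, and 1 cell 59 of 61 Cxcl9 UMIs in WT, so Cxcl9 is not read as a difference between lymphocytes.

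The share of lymphocytes with an Ifng UMI, each cell thinned to 1000 UMIs, was 3.97% (2.56–5.85) in Cd226-/-, 15.9% (12.5–19.7) in WT and 6.99% (4.26–10.7) in naive CD45+ skin; medians of 100 draws were 4.30%, 13.7% and 5.51%. Without thinning it was 9.77%, 25.2% and 13.6%, against 0.0714%, 0.0737% and 0% of the deeper fibroblasts. Il13 was seen in 9.27% of Cd226-/-, 4.81% of WT and 2.94% of naive lymphocytes after thinning (unthinned 15.2%, 10.1% and 6.25%). Il17a was seen in 33.9%, 31.3% and 6.62% (unthinned 37.3%, 33.7% and 10.3%). Gzmb was seen in 18.7%, 23.1% and 4.41% (unthinned 26.2%, 33.2% and 10.3%), and the regulatory T-cell gene Foxp3 in 0.828%, 0.481% and 2.21% (unthinned 1.82%, 2.40% and 4.78%). Unthinned shares in fibroblasts of Cd226-/- and WT were 0.143% and 0.147% for Il13, 2.75% and 2.06% for Il17a, 0.321% and 0.344% for Gzmb, and 0.0357% and 0.0246% for Foxp3. Over all immune cells, whatever their class, Ifng stood at 17.4 (15.8–19.2) in Cd226-/- and 65.1 (60.8–69.6) in WT, Gzma at 108 (104–113) and 349 (339–359), and Il13 at 47.0 (44.3–49.8) and 17.8 (15.6–20.2). The mix of lymphocytes differed too: 67.1% of the WT Ifng UMIs lay in 1 sub-cluster, which held 134 of 416 WT and 98 of 604 Cd226-/- lymphocytes. Sub-cluster 10, marked by Il17f, Il17a, Il13 and Areg, held 13 WT and 70 Cd226-/- lymphocytes, and sub-cluster 2, where Trdc was high, 55 and 122, so the type 2, type 17 and Trdc differences are not told apart from the mix. Within sub-cluster 0, the first named, thinned shares (medians of 100 draws) were 32.1% (24.3–40.7) in WT and 14.3% (8.04–22.8) in Cd226-/- for Ifng. For Gzmb they were 31.3% (23.6–39.9) and 17.3% (10.4–26.3).

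**Figure D2:**
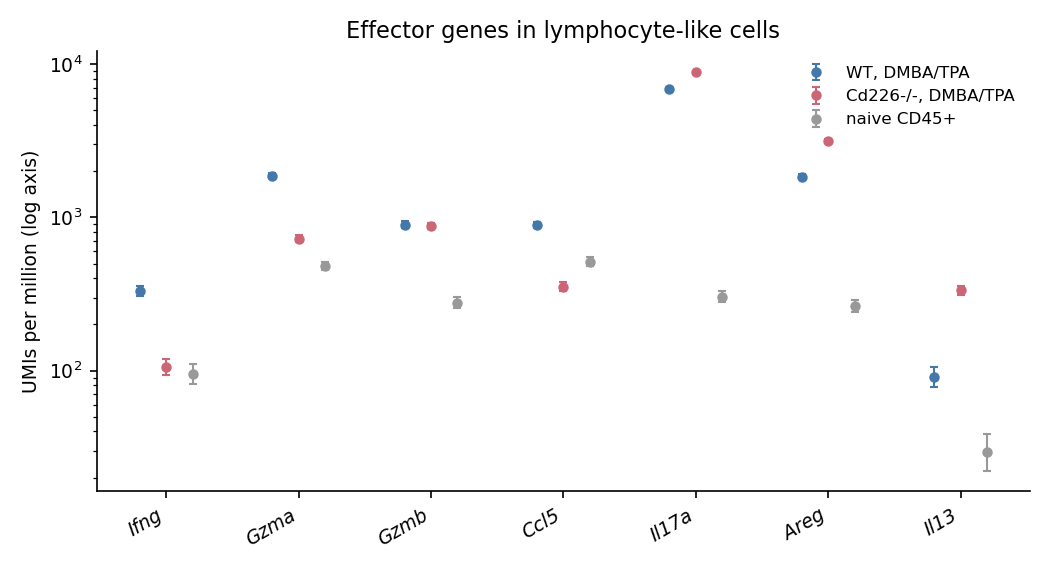
CPM (log axis) of 7 effector genes in lymphocytes of the WT and Cd226-/- DMBA/TPA libraries and the naive CD45+ library; points are summed counts, lines exact 95% Poisson intervals. Ifng lies at 332 in WT, 106 in Cd226-/- and 95.03 in naive skin; Il13 lies highest in Cd226-/-.

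Did cells that respond to IFN-γ follow? In macrophages and monocytes taken as one class, 27 of 30 IFN-γ response genes were lower in Cd226-/- (median log2 ratio −0.44, percentile 0). The chemokine Cxcl9 (3.24 against 75.9, 23.5-fold, 16.7–33.8), the immunity-related GTPase Iigp1 (9.88 against 27.1, 2.74-fold, 2.13–3.54) and Serpina3g (0.962 against 9.66, 10.04-fold, 5.18–21.3) led them. 8 of 9 MHC class II genes were lower as well (median log2 ratio −0.79, percentile 0), among them H2-Eb1 (1409.7 against 2790.0, 1.98-fold, 1.94–2.02) and Cd74 (4589 against 8502, 1.85-fold, 1.83–1.88), the invariant chain, and their transactivator Ciita (26.6 against 52.0, 1.96-fold, 1.66–2.31). Type I interferon genes were lower in 18 of 19 cases (median log2 ratio −0.45, percentile 0), for example Isg15 (102 against 182, 1.78-fold, 1.64–1.94) and Oasl2 (19.3 against 34.7, 1.80-fold, 1.47–2.19). Cell cycle genes were lower in 18 of 20 (median log2 ratio −0.82, percentile 0), for example Top2a (17.05 against 39.4, 2.31-fold, 1.89–2.82). Inflammatory genes split, 16 higher and 12 lower (median log2 ratio 0.054, percentile 66.3): Cxcl2 (8669 against 5592, 1.55-fold, 1.53–1.57), Ptgs2 (1251 against 827, 1.51-fold, 1.46–1.57) and Saa3 (827 against 463, 1.79-fold, 1.71–1.87) were higher, and Ccl5 (30.5 against 103, 3.37-fold, 2.94–3.86) and Ccl8 (2099 against 4009, 1.91-fold, 1.88–1.95) lower. By the ranking of single genes the first upward were the growth factor gene Ereg (12.6 against 3.34, 3.77-fold, 2.30–6.54), Glo1 (107 against 43.8, 2.44-fold, 2.12–2.82) and the chemokine Ccl1 (5.95 against 1.30, 4.57-fold, 2.10–11.8), and downward, after Cxcl9 and Serpina3g, Ctps2 (4.37 against 22.7, 5.18-fold, 3.70–7.35). 1 cell held 64 of 68 Ccl1 UMIs in Cd226-/-, and without the richest cell of each library Ccl1 did not differ.

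Monocytes formed 33.8 of the 46.4 points of this class in Cd226-/- and 22.8 of the 42.0 points in WT, so each part was also taken alone. IFN-γ response genes had medians of −0.29 in monocytes and −0.50 in macrophages, MHC class II genes −0.61 and −0.49, and type I genes −0.49 and −0.090. Inflammatory genes gave 0.083 and 0.045. Cell cycle genes gave 0.38 in monocytes, opposite to the whole class but from 5 members, and −0.52 from 17 in macrophages. Genes of alternative activation, 7 of 16 higher over the whole class (median log2 ratio −0.15, percentile 0.0900), had medians of 0.35 and 0.37 in the parts. Over the class Chil3 (608 against 361, 1.69-fold, 1.60–1.77) and Trem2 (106 against 77.1, 1.38-fold, 1.23–1.54) were higher and Arg1 (14.0 against 23.6, 1.69-fold, 1.32–2.14) and Retnla (276 against 447, 1.62-fold, 1.53–1.71) lower. Classical activation genes split 7 to 7 (median log2 ratio −0.14, percentile 2.02, −0.036 and −0.53 in the parts), Cxcl9 being the member farthest from equality and the class median 0.061 with the richest cell of each gene left out. Ccl1 was lower, not higher, with each library clustered on its own. Other lists were lower in the whole class too: 14 of 19 dissociation stress genes (median log2 ratio −0.19, percentile 0.0200) and, of lists made for lymphocytes, 9 of 13 cytotoxic and type 1 genes (median log2 ratio −1.29, percentile 0) and 4 of 7 regulatory T-cell genes (median log2 ratio −0.81, percentile 0.0700). Of lists made for fibroblasts, 19 of 22 collagen and matrix genes (median log2 ratio −1.20, percentile 0) and 12 of 14 proteases and inhibitors (median log2 ratio −0.88, percentile 0) were lower in the class. Dissociation stress genes were also lower in fibroblasts (14 of 19, median log2 ratio −0.24, percentile 0), Langerhans cells (17 of 19, median log2 ratio −0.28, percentile 0) and neutrophils (13 of 18, median log2 ratio −0.11, percentile 18.1), but not in lymphocytes (8 of 18, median log2 ratio 0.12, percentile 96.8). At a finer clustering both lymphocyte lists turned just above 0 in phagocytes. The stress median turned positive in Langerhans cells with each library clustered on its own and in neutrophils under trimmed-mean scaling. RNA at the level of fibroblast markers made up an estimated 0.848% of phagocyte counts in Cd226-/- and 1.98% in WT, and RNA at the level of T-cell markers 0.850% and 1.52%.

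How did the IFN-γ list differ in the other immune cells? In lymphocytes themselves 18 of 26 members were lower (median log2 ratio −0.20, percentile 0), among them Irf1 (39.5 against 67.0, 1.70-fold, 1.29–2.23) and Psmb9 (150.3 against 227, 1.51-fold, 1.31–1.74). Langerhans cells had 22 of 29 lower (median log2 ratio −0.19, percentile 0.490), with Iigp1 (1.66 against 21.2, 12.8-fold, 5.53–36.1) and Cxcl9 (6.91 against 40.5, 5.86-fold, 3.78–9.44) far ahead of the rest. Lists made for other cells were farther below WT in them: 17 of 17 collagen and matrix genes (median log2 ratio −2.33, percentile 0), 7 of 8 type 17 genes (median log2 ratio −0.84, percentile 0), 11 of 15 cytotoxic and type 1 genes (median log2 ratio −0.67, percentile 0) and 13 of 15 keratinocyte wound genes (median log2 ratio −0.78, percentile 0, positive with each library clustered on its own). With the richest cell of each gene left out, the type 17 and wound medians were −0.29 and −0.080. Their MHC class II genes were level (6 of 11 higher, median log2 ratio 0.029, percentile 65.7, H2-Aa 14264 against 12934, Ciita 86.8 against 123). A half-width given for a list is that of the counting interval of its middle gene or genes. It is not a spread of the list. The IFN-γ medians of lymphocytes and Langerhans cells lie within it (0.37 and 0.28). Neutrophils had 15 of 16 IFN-γ response genes lower (median log2 ratio −0.45, percentile 0.110), such as Gbp7 (52.1 against 89.5, 1.72-fold, 1.17–2.54). So were 10 of 10 type I genes (median log2 ratio −0.43, percentile 1.56), such as Rsad2 (295 against 580.1, 1.96-fold, 1.68–2.29). Scaling by trimmed means raises all log2 ratios of neutrophils by 0.18 against total counts. The IFN-γ median is then −0.27, within its half-width of 0.35. Of lists made for other cells, 7 of 7 collagen and matrix genes were lower (median log2 ratio −1.58, percentile 0) and 3 of 3 type 17 genes higher (median log2 ratio 5.75, percentile 99.995). 1 and the same cell held 127 of 135 Il17a, 125 of 127 Il17f and 158 of 160 Il22 UMIs of Cd226-/- neutrophils, so the type 17 median is not read as a property of the class.

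By the ranking of single genes, Langerhans cells of Cd226-/- were highest for the enkephalin precursor Penk (82.4 against 6.35, 12.99-fold, 8.07–22.2), Gpnmb (21.8 against 6.70, 3.26-fold, 1.96–5.70) and Glo1 (85.2 against 38.4, 2.22-fold, 1.78–2.78). They were lowest for Sostdc1 (0.276 against 37.4, 135-fold, 23.7–5388), Igfbp2 (0.553 against 20.1, 36.3-fold, 9.61–307) and Sfrp2 (0.829 against 21.9, 26.4-fold, 8.61–131). 1 cell held 296 of 298 Penk UMIs in Cd226-/-, and in WT 1 cell held 105 of 106 Sostdc1 and 1 cell 56 of 57 Igfbp2 UMIs, so Penk, Sostdc1 and Igfbp2 are not read as differences between Langerhans cells. Sostdc1, Igfbp2 and Sfrp2 stood at 5882, 234 and 763 per 1000000 in unnamed non-immune WT cells, a source of free RNA; with those cells weighed as well, Lce3e, Retnla and Lyz1 take their place. By the same ranking, which leaves out genes under 0.1 times the level of the class highest for them, neutrophils of Cd226-/- were highest for Coch (156 against 1.49, 105-fold, 18.5–4164), Ngp (536 against 133, 4.04-fold, 3.22–5.11) and Retnlg (5552 against 1924, 2.89-fold, 2.72–3.07), the latter 2 granule or secreted genes of neutrophils, while 1 cell held 155 of 156 Coch UMIs. They were lowest for Retnla (0 against 106, at least 35.2-fold), Fn1 (33.0 against 254, 7.67-fold, 5.26–11.5) and Igfbp5 (16.0 against 76.1, 4.75-fold, 2.66–8.92). Fibroblast-level RNA was an estimated 1.15% of neutrophil counts in Cd226-/- and 2.29% in WT. Fn1 was high in fibroblasts (2604 against 2043 there) and is also among the fixed monocyte markers, and the source of its 254 in WT neutrophils was not tested. Inflammatory genes were lower in 16 of 22 cases in Langerhans cells (median log2 ratio −0.49, percentile 0), led by the fibroblast-type chemokines Cxcl12 (6.36 against 20.1, 3.16-fold, 1.92–5.37) and Ccl2 (96.8 against 241, 2.495-fold, 2.19–2.85), in cells where fibroblast-level RNA was 0.591% against 3.84%. This median and Ccl2 turned positive with each library clustered on its own. In neutrophils 10 of 16 were lower (median log2 ratio −0.16, percentile 6.12, Saa3 47.1 against 170.0, Cxcl2 92915 against 88038), with 1 cell holding 81 of 114 Saa3 UMIs in WT and Saa3 turned when doublets were kept, a median that turned positive under trimmed-mean scaling and with each library clustered on its own. In lymphocytes it was 9 of 16 (median log2 ratio −0.085, percentile 6.55, 1.16 with each library clustered on its own and 0.052 with the richest cell of each gene left out), Ccl5 among the lower and Cxcl2 (508 against 176, 2.88-fold, 2.55–3.26) among the higher ones.

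**Figure D3:**
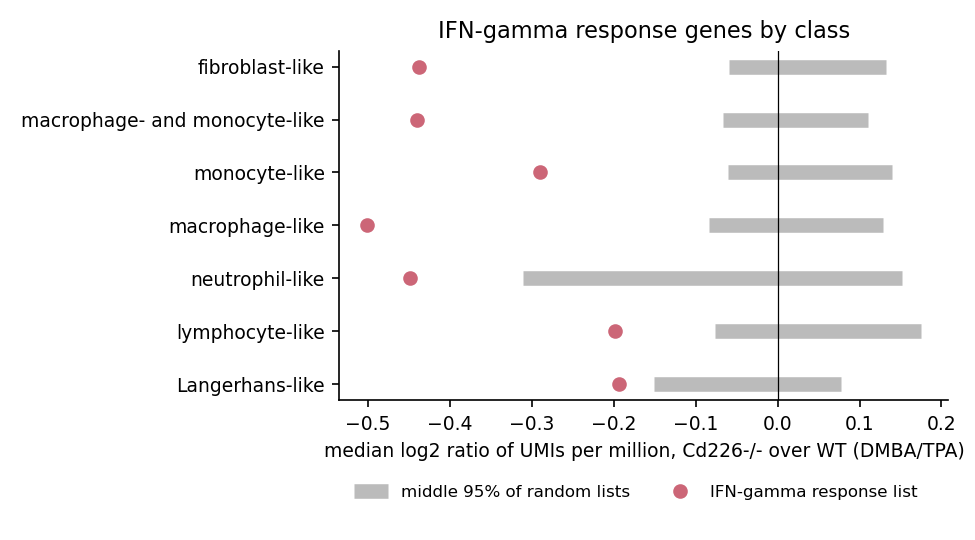
Median log2 ratio of IFN-γ response genes, Cd226-/- over WT after DMBA/TPA (horizontal axis), by class. Points are list medians, bars the middle 95% of medians of 10000 random lists of like expression. All 7 points lie below 0, from −0.50 in macrophages to −0.19 in Langerhans cells.

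How did fibroblasts, the largest non-immune class, differ between genotypes? 25 of 30 inflammatory cytokine and chemokine genes were higher in Cd226-/- (median log2 ratio 0.60, percentile 100): the acute-phase gene Saa3 (2809 against 1078, 2.61-fold, 2.58–2.63), Cxcl14 (2050.1 against 1209, 1.70-fold, 1.68–1.71) and the growth factors Csf3 (26.7 against 7.80, 3.43-fold, 3.03–3.88) and Csf2 (3.21 against 0.463, 6.94-fold, 4.34–11.6). Ccl5 and Ptgs2 (61.4 against 87.3) were among the 5 lower ones. IFN-γ response genes were lower in 25 of 31 cases (median log2 ratio −0.44, percentile 0), with Cxcl9 (7.63 against 31.8, 4.16-fold, 3.67–4.74), Gbp4 (4.24 against 16.2, 3.83-fold, 3.22–4.57) and Gbp2 (46.8 against 77.8, 1.66-fold, 1.57–1.76), while Iigp1 was level (178 against 179). Type I interferon genes did not follow: 14 of 20 were higher (median log2 ratio 0.14, percentile 94.8), such as Ifi27l2a (1138 against 742, 1.53-fold, 1.51–1.56). All 23 cell cycle genes were higher (median log2 ratio 1.13, percentile 100), for example Ccnb2 (7.37 against 2.05, 3.59-fold, 2.83–4.60) and Birc5 (12.2 against 3.94, 3.09-fold, 2.59–3.69). So were 14 of 16 hypoxia and glycolysis genes (median log2 ratio 0.29, percentile 99.96), the peptide hormone gene Adm (941 against 281, 3.35-fold, 3.28–3.42) most of all, with Vegfa (45.7 against 76.3, 1.67-fold, 1.58–1.77) against the trend. 15 of 22 collagen and matrix genes were lower (median log2 ratio −0.20, percentile 0), including Tnc (128 against 261, 2.04-fold, 1.97–2.11), Postn (637 against 1219.5, 1.91-fold, 1.89–1.94) and Col1a1 (10196 against 15985, 1.57-fold, 1.56–1.57), with Col12a1 (114 against 65.6, 1.74-fold, 1.66–1.82) higher. Proteases and their inhibitors split 7 to 6 (median log2 ratio 0.088, percentile 64.5), with Mmp3 (1319.8 against 842, 1.57-fold, 1.55–1.59) higher and Mmp19 (78.1 against 105, 1.35-fold, 1.29–1.41) lower. The first by the ranking of single genes were Jchain (2.92 against 0.110, 26.5-fold, 11.0–83.2), Reg1 (7.29 against 0.507, 14.4-fold, 9.39–23.1) and Mgarp (6.76 against 0.529, 12.8-fold, 8.40–20.3) upward. Downward they were Car3 (0.474 against 9.70, 20.5-fold, 12.8–34.9), Krt20 (0.421 against 6.68, 15.9-fold, 9.61–28.1) and Zhx2 (0.895 against 10.2, 11.4-fold, 8.03–16.6). 1 cell held 110 of 111 Jchain UMIs in Cd226-/-, so Jchain is not read as a difference between fibroblasts.

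All 7 MHC class II genes were also higher in fibroblasts of Cd226-/- (median log2 ratio 0.96, percentile 100, smaller with cells weighted equally), Cd74 (41.1 against 21.2, 1.94-fold, 1.79–2.11) and H2-Aa (27.4 against 13.6, 2.01-fold, 1.82–2.23) among them, in a library whose immune share was 50.01% against 27.3%. The same holds for cytokines that phagocytes carry at far higher levels: Ccl4 (24.7 against 7.34, 3.37-fold, 2.97–3.83) and Il1b (16.8 against 7.38, 2.28-fold, 1.99–2.61) stood at 2321 and 3112 in phagocytes of Cd226-/-, whereas Saa3 was higher in fibroblasts than in phagocytes (827). The mix of fibroblast clusters differed as well: cluster 8 was the most numerous in WT and clusters 3, 4 and 2 in Cd226-/-. With each library clustered on its own the cell cycle median was smaller and still positive.

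3 genes outside the lists are given in more than 1 class. Glo1, which encodes the methylglyoxal-detoxifying enzyme glyoxalase 1 (chromosome 17:30584936-30626871, GRCm38, GENCODE vM21), was higher in Cd226-/- in fibroblasts (156 against 71.1, 2.19-fold, 2.10–2.29) and lymphocytes (133 against 42.4, 3.13-fold, 2.44–4.04), as in phagocytes and Langerhans cells; neutrophils had 6 and 4 UMIs. Its neighbours Btbd9 (1.72-fold, 1.54–1.93) and Dnah8 (2.46-fold, 1.60–3.85) were higher in fibroblasts too. Btbd9 was 2.04-fold (1.36–3.12) higher in lymphocytes, 1.39-fold (1.11–1.74) in phagocytes, 1.84-fold (1.07–3.29) in neutrophils and 1.22-fold (0.890–1.67) in Langerhans cells, where its interval includes equality and Glo1 was 2.22-fold higher. In naive skin Glo1 was near the WT level in fibroblasts (62.6) and near the Cd226-/- level in lymphocytes (147) and phagocytes (96.6). Zhx2, a zinc-finger and homeobox repressor gene, stood at 0.895 (0.619–1.25) in Cd226-/-, 10.2 (9.27–11.2) in WT and 17.3 (16.3–18.3) in naive fibroblasts. In lymphocytes it was level (3.70 against 3.66), and in phagocytes the intervals overlapped, but in Langerhans cells they lay apart, at 0.553 (0.0670–1.998) against 6.70 (4.03–10.5). Ctps2, for a CTP synthase, stood at 3.45 (2.88–4.09), 20.2 (18.9–21.5) and 10.2 (9.47–11.0) in fibroblasts, and at 3.70 (1.69–7.03) in Cd226-/- and 15.2 (10.2–21.8) in WT lymphocytes.

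The ligands of CD226 and the receptors that share them were read beside it. In fibroblasts the ligand gene Pvr (37.5 against 21.8, 1.72-fold, 1.59–1.87) was higher in Cd226-/-; Nectin1 (11.1 against 15.5, 1.40-fold, 1.24–1.59), Nectin2 (5.39 against 4.05, 1.33-fold, 1.08–1.63), Nectin3 (33.4 against 33.9, 1.02-fold, 0.942–1.09) and Cadm1 (1.13 against 3.37, 2.98-fold, 2.11–4.28) completed the family there. In lymphocytes Cd96 (52.7 against 60.2, 1.14-fold, 0.880–1.48), Crtam (39.9 against 38.2, 1.05-fold, 0.763–1.44) and Pvr (17.7 against 10.5, 1.69-fold, 0.973–3.03) had enough counts, and Tigit did not. In phagocytes Cd226 itself was 1.66 against 5.94 (3.58-fold, 1.97–6.68), beside Pvr (38.0 against 27.7, 1.37-fold, 1.14–1.67), Nectin1 (6.21 against 10.4, 1.68-fold, 1.16–2.41), Nectin2 (4.11 against 6.13, 1.49-fold, 0.926–2.38), Nectin4 (6.56 against 7.98, 1.22-fold, 0.817–1.79) and Cadm1 (5.16 against 7.61, 1.48-fold, 0.966–2.24). Checkpoint genes of lymphocytes were near level between the genotypes, 9 of 13 higher (median log2 ratio 0.050, percentile 65.8): Pdcd1 208 against 219, Ctla4 280.3 against 256 and Tnfrsf9 (569 against 401, 1.42-fold, 1.30–1.55). Cell cycle genes of lymphocytes were lower in 17 of 21 cases (median log2 ratio −0.27, percentile 0), Ube2c (79.0 against 161, 2.03-fold, 1.69–2.45) among them, with the sign turned at a finer clustering. Type I genes split 3 to 4 (median log2 ratio −0.057, percentile 17.4), with Ifi27l2a (131 against 267, 2.04-fold, 1.77–2.36) lower and Bst2 (133 against 96.3, 1.38-fold, 1.15–1.66) higher, the latter not with each library clustered on its own.

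How did fibroblasts after DMBA/TPA differ from those of naive skin? Levels are now given for WT, Cd226-/- and naive skin, with the folds of WT and then Cd226-/- over or under naive. All inflammatory genes measured were higher, 27 in WT and 28 in Cd226-/- (median log2 ratios 2.87 and 3.86, percentiles 100 and 100). Cxcl5 (WT 73.6, Cd226-/- 90.3, naive 0.0564, 1307-fold, 509.8–4798 and 1602-fold, 625–5884), Saa3 (WT 1078, Cd226-/- 2809, naive 4.49, 239.9-fold, 215–269 and 625-fold, 560.0–699.9) and Lcn2 (WT 84.7, Cd226-/- 130.4, naive 0.211, 401-fold, 243–717 and 617-fold, 374–1104) were far higher. Csf3 (26.7 against 0, at least 632-fold) in Cd226-/- was read against no UMI in naive skin. IFN-γ response genes were higher in 28 of 31 and 25 of 31 (0.86 and 0.36, percentiles 100 and 90.6), for example Iigp1 (WT 179, Cd226-/- 178, naive 30.04, 5.98-fold, 5.70–6.27 and 5.93-fold, 5.64–6.22) and Cxcl9 (WT 31.8, Cd226-/- 7.63, naive 1.24, 25.6-fold, 20.6–32.1 and 6.15-fold, 4.83–7.90). The matrix glycoprotein Tnc (WT 261, Cd226-/- 128, naive 0.606, 431-fold, 319.9–596 and 211-fold, 157–293), the protease inhibitor Timp1 (WT 897, Cd226-/- 964, naive 38.4, 23.4-fold, 22.5–24.3 and 25.1-fold, 24.2–26.1) and the alarmin Il33 (WT 285, Cd226-/- 375, naive 42.0, 6.78-fold, 6.52–7.06 and 8.94-fold, 8.59–9.30) were higher as well. All 23 cell cycle genes were higher in both (1.498 and 2.72, percentiles 100 and 100), for example Top2a (WT 6.66, Cd226-/- 13.1, naive 1.45, 4.59-fold, 3.66–5.79 and 9.05-fold, 7.30–11.3). So were 14 of 16 and 14 of 16 hypoxia and glycolysis genes (0.72 and 1.06, percentiles 99.96 and 99.99), for example Ldha (WT 382, Cd226-/- 537, naive 107, 3.58-fold, 3.49–3.68 and 5.04-fold, 4.91–5.17). Proteases and their inhibitors were higher in 8 of 13 and 8 of 13 (0.54 and 0.62, percentiles 97.7 and 97.9), the WT median smaller under trimmed-mean scaling. Timp1 was among them.

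Collagen and matrix genes were lower in 13 of 22 and 14 of 22 cases (−0.19 and −0.18, percentiles 0.410 and 0.25, the WT median farther from 0 under trimmed-mean scaling), led by the main collagen genes Col1a1 (WT 15985, Cd226-/- 10196, naive 52333, 3.27-fold, 3.27–3.28 and 5.13-fold, 5.12–5.15) and Col1a2 (WT 19708, Cd226-/- 13364, naive 62757, 3.18-fold, 3.18–3.19 and 4.70-fold, 4.68–4.71). Lowest by the ranking of single genes were Cfd (WT 0.198, Cd226-/- 0.105, naive 23.8, 120.0-fold, 63.0–263 and 226-fold, 88.1–831) and Colq (WT 0.176, Cd226-/- 0.0263, naive 17.2, 97.6-fold, 49.4–227 and 654-fold, 117–25844), the first an adipocyte complement factor, with Adcy1 (0.617 against 43.2, 70.0-fold, 48.4–106) in WT and Adra2c (0 against 5.33, at least 67.5-fold) in Cd226-/-. Type I interferon genes were higher in 14 of 20 and 15 of 21 (0.21 and 0.30, percentiles 57.2 and 74.5), Ifi204 (WT 302, Cd226-/- 417, naive 113, 2.66-fold, 2.59–2.74 and 3.68-fold, 3.58–3.78) among them, and the WT median turned negative under trimmed-mean scaling. MHC class II genes were higher in all 7 (2.92 and 4.14, percentiles 100 and 100), Cd74 (WT 21.2, Cd226-/- 41.1, naive 2.32, 9.10-fold, 7.71–10.8 and 17.7-fold, 15.04–20.9) among them, with immune shares of 27.3% in WT, 50.01% in Cd226-/- and 1.04% in naive CD45- skin. Trimmed-mean scaling moves all log2 ratios of fibroblasts by −0.22 in WT and −0.23 in Cd226-/-, and the medians are to be read against these shifts. Most naive fibroblasts lay in clusters 0, 1, 7 and 10 and most treated ones in clusters 2, 3, 4 and 8, although cluster 2 held 794 WT, 717 Cd226-/- and 961 naive CD45- cells.

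**Figure D4:**
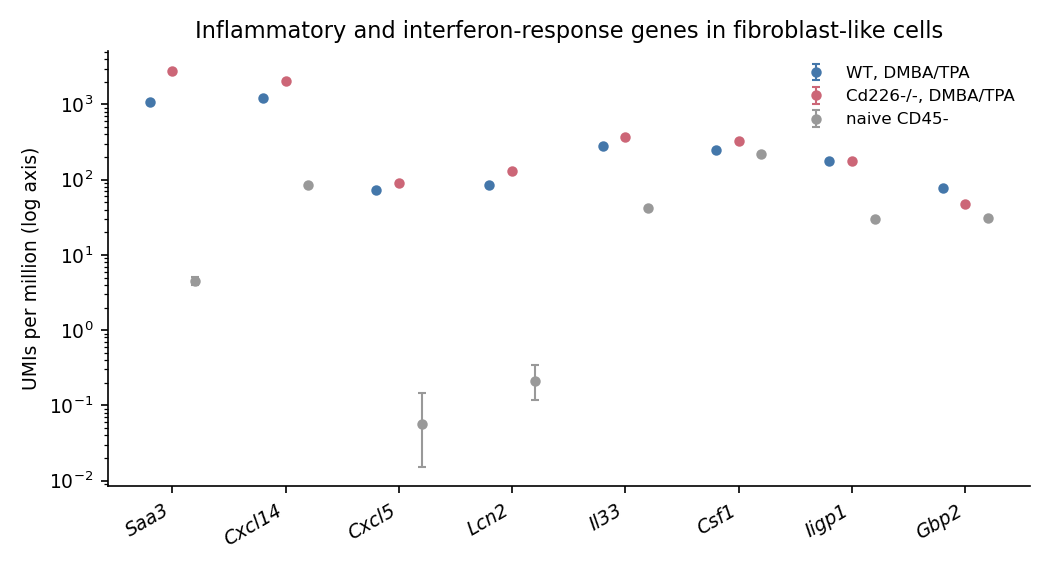
CPM (log axis) of 8 inflammatory and interferon-response genes in fibroblasts of the WT and Cd226-/- DMBA/TPA libraries and the naive CD45- library; points are summed counts, lines exact 95% Poisson intervals. Saa3 lies at 2809 in Cd226-/-, 1078 in WT and 4.49 in naive skin.

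Which lymphocyte genes differed between treated and naive skin? Il22 (WT 4807, Cd226-/- 4032, naive 9.23, 521-fold, 325–894 and 437-fold, 273–750.1), Il17f (WT 5473, Cd226-/- 5530.2, naive 48.3, 113-fold, 91.9–141 and 114-fold, 92.9–143) and Il17a (WT 6886, Cd226-/- 8960.1, naive 304, 22.6-fold, 20.8–24.7 and 29.5-fold, 27.1–32.1) were far higher than in naive skin. So was Ifitm1 (1843 against 23.9, 77.2-fold, 57.3–106) in WT. Il22, Il17f and Il17a belong to the type 17 list, and the rest of that list did not follow. Only 6 of 14 and 7 of 14 of its genes were higher (−0.52 and 0.21, percentiles 0.06 and 96.7), and the WT median turned positive when only genes with 200 UMIs were used. Sox13 (WT 5.23, Cd226-/- 10.7, naive 47.8, 9.13-fold, 4.74–19.7 and 4.46-fold, 2.85–7.21) and Ccr6 (WT 30.9, Cd226-/- 33.8, naive 91.8, 2.97-fold, 2.20–4.07 and 2.72-fold, 2.08–3.58) were lower. Cytotoxic and type 1 genes were higher in 15 of 21 and 15 of 21 (0.69 and 0.20, percentiles 100 and 98.0). Over the class the genotypes lay farther apart at Ifng and Gzma than at Gzmb, as Ifng (WT 332, Cd226-/- 106, naive 95.03, 3.50-fold, 2.95–4.16 and 1.11-fold, 0.915–1.36), Gzma (WT 1877, Cd226-/- 729, naive 482, 3.90-fold, 3.62–4.1998 and 1.51-fold, 1.39–1.64) and Gzmb (WT 898, Cd226-/- 883, naive 278, 3.23-fold, 2.92–3.57 and 3.18-fold, 2.88–3.51) show. Gzmf (55.6 against 0, at least 34.1-fold) in Cd226-/- had no naive UMI. Checkpoint genes were higher in 9 of 12 and 9 of 12 (0.59 and 0.54, percentiles 100 and 99.9), with Havcr2 (WT 103, Cd226-/- 115, naive 7.06, 14.5-fold, 8.30–27.8 and 16.3-fold, 9.36–30.9), Tnfrsf9 (WT 401, Cd226-/- 569, naive 63.5, 6.32-fold, 5.20–7.74 and 8.96-fold, 7.42–10.9) and Pdcd1 (WT 219, Cd226-/- 208, naive 66.8, 3.28-fold, 2.67–4.04 and 3.11-fold, 2.55–3.82). The type 2 list differed between the genotypes, 2 of 6 higher in WT and 4 of 8 in Cd226-/- (−1.13 and 1.04, percentiles 0 and 100). Areg (WT 1849, Cd226-/- 3176, naive 263, 7.04-fold, 6.40–7.75 and 12.1-fold, 11.0–13.3) and Il13 (WT 91.1, Cd226-/- 333, naive 29.3, 3.11-fold, 2.28–4.30 and 11.4-fold, 8.63–15.3) were higher in both, Il9r (WT 3.66, Cd226-/- 3.70, naive 23.3, 6.37-fold, 2.84–16.8 and 6.30-fold, 3.03–14.7) lower. With so few members the WT median turned positive at a finer clustering and with the richest cell of each gene left out (0.49), and the Cd226-/- median negative with each library clustered on its own. Type I interferon genes were lower in all 11 (−1.13 and −1.46, percentiles 0 and 0), with Rsad2 (WT 0.523, Cd226-/- 2.06, naive 60.8, 116-fold, 20.4–4630.1 and 29.5-fold, 12.3–92.8) and, in Cd226-/-, Usp18 (1.65 against 24.98, 15.2-fold, 5.54–58.0) lowest. IFN-γ response genes were higher in 16 of 26 and 9 of 25 (0.086 and −0.097, percentiles 95.3 and 26.0), Irf8 (WT 76.9, Cd226-/- 133, naive 39.1, 1.97-fold, 1.47–2.65 and 3.41-fold, 2.64–4.47) being higher in both, though not with each library clustered on its own.

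Further genes far below the naive level in lymphocytes were the clock repressor Nr1d1 (3.14 against 37.5, 11.9-fold, 5.21–33.6) and Tmem64 (23.6 against 156, 6.64-fold, 4.84–9.31) in WT. In Cd226-/- they were the skin-homing receptor Ccr10 (2.47 against 43.4, 17.6-fold, 7.73–49.4) and the histone gene Hist1h2bc (4.53 against 38.6, 8.51-fold, 4.48–17.8). Inflammatory genes of lymphocytes were higher in 8 of 12 and 10 of 14 (0.44 and 0.22, percentiles 99.9 and 96.7), for example Csf1 (WT 52.3, Cd226-/- 43.6, naive 11.9, 4.38-fold, 2.74–7.30 and 3.65-fold, 2.29–6.07), the WT median being negative under a looser cell filter and with each library clustered on its own. Cell cycle genes were lower in 17 of 21 and 20 of 21 (−0.37 and −0.62, percentiles 0.5 and 0), for example Mcm2 (WT 17.3, Cd226-/- 17.7, naive 41.3, 2.39-fold, 1.57–3.71 and 2.33-fold, 1.58–3.47), the WT median being positive with cells weighted equally. Trimmed-mean scaling moves the WT log2 ratios of this class by 0.12. In naive lymphocytes Glo1 (147), Btbd9 (39.6) and Ctps2 (4.89) stood nearer to treated Cd226-/- than to WT cells. In phagocytes Glo1 and Ctps2 did too, but not Btbd9. In naive fibroblasts Glo1 (62.6) and Btbd9 (10.3) stood nearer to WT, and Ctps2 and Dnah8 lay between. Both naive libraries are labelled as mixes, but which genotype their values stand for is open, Ifng (95.03) included.

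How did macrophages and monocytes of treated skin differ from naive ones? Against naive skin 24 of 28 and 22 of 28 inflammatory genes were higher (0.99 and 0.67, percentiles 100 and 100), with Saa3 (WT 463, Cd226-/- 827, naive 29.7, 15.6-fold, 14.4–16.96 and 27.9-fold, 25.8–30.1), Il1b (WT 2742, Cd226-/- 3112, naive 684, 4.01-fold, 3.92–4.10 and 4.55-fold, 4.47–4.64) and Lcn2 (WT 81.3, Cd226-/- 110.3, naive 14.3, 5.70-fold, 4.94–6.57 and 7.73-fold, 6.86–8.72). By the ranking of single genes Ifitm1 (WT 425, Cd226-/- 917, naive 28.8, 14.7-fold, 13.5–16.0 and 31.8-fold, 29.5–34.3), the activin gene Inhba (118 against 12.0, 9.86-fold, 8.58–11.4) in WT and Ccl1 (5.95 against 0.0404, 147-fold, 25.5–5891) in Cd226-/- stood out as well, though 1 cell held 64 of 68 Ccl1 UMIs. Inhba reached 1389.5 per 1000000 in unnamed non-immune WT cells. Type I interferon genes were lower in all 20 (−1.60 and −2.17, percentiles 0 and 0), such as Rsad2 (WT 60.0, Cd226-/- 43.1, naive 337, 5.62-fold, 5.03–6.31 and 7.83-fold, 7.15–8.59) and Ifit2 (WT 12.3, Cd226-/- 7.17, naive 114, 9.29-fold, 7.28–12.0 and 15.9-fold, 12.8–20.04). The lipid-handling genes Apoe (WT 10180.0, Cd226-/- 8332, naive 20147, 1.98-fold, 1.96–1.997 and 2.42-fold, 2.40–2.43) and Trem2 (WT 77.1, Cd226-/- 106, naive 311, 4.04-fold, 3.66–4.47 and 2.94-fold, 2.76–3.12) were lower too. By that ranking the lowest were Rapsn (0.186 against 15.1, 81.2-fold, 14.5–3217), Lpl (39.0 against 528, 13.5-fold, 11.8–15.6) and Kdr (1.11 against 24.5, 22.0-fold, 10.03–60.1) in WT. In Cd226-/- they were P3h2 (0.350 against 19.3, 55.2-fold, 21.4–203), Pla2g2d (3.24 against 62.7, 19.4-fold, 14.0–27.6) and Ifit1bl1 (0.262 against 10.7, 40.9-fold, 13.8–199). IFN-γ response genes were lower in 18 of 31 and 23 of 31 (−0.17 and −0.65, percentiles 4.95 and 0), such as Cxcl10 (WT 63.5, Cd226-/- 42.1, naive 220.2, 3.47-fold, 3.11–3.88 and 5.23-fold, 4.76–5.75) and Irgm1 (WT 29.0, Cd226-/- 19.5, naive 69.2, 2.39-fold, 2.03–2.83 and 3.55-fold, 3.09–4.10). MHC class II genes were lower in 4 of 11 and 11 of 11 (0.062 and −0.82, percentiles 58.8 and 0.255), Cd74 (WT 8502, Cd226-/- 4589, naive 8142, 1.04-fold, 1.03–1.05 and 1.77-fold, 1.76–1.79) being just above naive in WT and below it in Cd226-/-, and with each library clustered on its own the WT median and WT Cd74 turned just below 0. Cell cycle genes were lower in 10 of 24 and 21 of 24 (0.17 and −0.67, percentiles 99.5 and 0.780), Stmn1 (WT 18.6, Cd226-/- 7.69, naive 39.1, 2.11-fold, 1.71–2.61 and 5.08-fold, 4.08–6.40) in both.

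The parts were read alone, since naive skin held 4.82% monocytes and 58.5% macrophages among immune cells. IFN-γ response genes had medians for WT and Cd226-/- of 0.70 and 0.37 in monocytes and 0.084 and −0.61 in macrophages. Over the class they were −0.17 and −0.65. MHC class II genes gave 0.64 and 0.033 in monocytes and 0.52 and 0.029 in macrophages. Cell cycle genes gave −0.16 and −0.10 in monocytes (3 and 5 members) and 1.04 and 0.55 in macrophages (23 and 24). Inflammatory genes gave −0.076 and 0.12 in monocytes and 0.68 and 0.56 in macrophages, and type I interferon genes −0.46 and −1.18 in monocytes and −1.66 and −1.75 in macrophages, so that only the last list was lower in every part and genotype. Genes of alternative activation were lower in 10 of 16 and 9 of 16 over the class (−0.15 and −0.34, percentiles 3.71 and 0.26) and higher in the parts (0.47 and 0.40 in monocytes and 0.13 and 0.27 in macrophages). Chil3 (WT 361, Cd226-/- 608, naive 82.8, 4.35-fold, 4.09–4.64 and 7.34-fold, 6.98–7.71) was higher and Folr2 (WT 284, Cd226-/- 225, naive 682, 2.40-fold, 2.28–2.53 and 3.03-fold, 2.91–3.16) lower over the class, the WT list median turning positive with each library clustered on its own. Classical activation genes were higher in 8 of 13 and 7 of 14 (1.01 and 0.072, percentiles 100 and 83.6) and in the parts had medians of −0.037 and −0.030 in monocytes and 0.46 and −0.011 in macrophages, the class median of Cd226-/- being −0.29 with the richest cell of each gene left out, for example Ptgs2 (WT 827, Cd226-/- 1251, naive 297, 2.79-fold, 2.68–2.89 and 4.22-fold, 4.10–4.34). Lists made for other cells were higher in the class as well: 19 of 19 and 21 of 21 collagen and matrix genes (2.86 and 1.502, percentiles 100 and 100), 5 of 7 and 5 of 7 type 17 genes (2.48 and 1.47, percentiles 100 and 100) and 12 of 14 and 8 of 12 cytotoxic and type 1 genes (1.83 and 0.97, percentiles 100 and 100). At a finer clustering the type 17 median turned negative in WT and the cytotoxic median in Cd226-/-, and with the richest cell of each gene left out the type 17 medians were 0.20 and 0.82. The treated libraries hold CD45- cells and the naive one was sorted for CD45+, so RNA from other cells can differ between them.

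How did neutrophils, dendritic cells and vessels of treated skin differ from naive ones? Neutrophils come first. Type I genes were lower in all 18 (−2.18 and −3.18, percentiles 0 and 0), with Ifit3 (WT 10.4, Cd226-/- 6.01, naive 324, 31.0-fold, 14.96–77.5 and 53.9-fold, 24.6–148), Ifit3b (WT 14.9, Cd226-/- 8.01, naive 395, 26.5-fold, 14.3–55.4 and 49.2-fold, 24.8–115) and Rsad2 (WT 580.1, Cd226-/- 295, naive 4496, 7.75-fold, 6.998–8.60 and 15.2-fold, 13.5–17.2). IFN-γ response genes were lower in 20 of 22 and 21 of 22 (−0.78 and −1.31, percentiles 0.330 and 0), Cxcl10 (WT 8.95, Cd226-/- 28.0, naive 1041, 116-fold, 53.4–318 and 37.1-fold, 25.6–56.0) foremost. Inflammatory genes were higher in 14 of 17 and 11 of 16 (1.05 and 0.82, percentiles 100 and 100), with Cxcl3 (WT 6669, Cd226-/- 6442, naive 696, 9.58-fold, 8.98–10.2 and 9.25-fold, 8.69–9.85) and, outside the list, the growth factor Hbegf (WT 291, Cd226-/- 244, naive 12.5, 23.3-fold, 14.9–38.6 and 19.6-fold, 12.5–32.3). Egln3 (68.6 against 5.34, 12.8-fold, 6.21–29.9) in WT and Coch (156 against 0, at least 87.8-fold) and Ngp (536 against 35.6, 15.1-fold, 11.5–19.999) in Cd226-/- also led the ranking of single genes, Coch from 1 cell as above. 3 of 5 type 17 genes were higher in Cd226-/- (median log2 ratio 6.16, percentile 100), with nearly all Il17a, Il17f and Il22 UMIs from 1 cell. Dendritic cells, numerous enough in Cd226-/- alone, were higher for Ifitm1 (1498 against 130.1, 11.5-fold, 10.4–12.7), Ramp3 (44.0 against 2.67, 16.5-fold, 8.51–35.7) and Dmkn (152 against 24.3, 6.26-fold, 4.92–8.03). They were lower for Fcna (0.557 against 13.3, 24.0-fold, 4.11–965), Hr (1.67 against 19.998, 12.0-fold, 3.94–59.4) and Cd207 (13.4 against 79.2, 5.93-fold, 3.91–9.40). Their type I genes were lower in all 15 (median log2 ratio −0.92, percentile 0), for example Isg15 (42.9 against 109.6, 2.56-fold, 2.0003–3.31). Of IFN-γ response genes 14 of 21 were lower (median log2 ratio −0.13, percentile 5.84), for example Irgm1 (15.6 against 25.3, 1.63-fold, 1.06–2.57), with Cd274 (22.8 against 10.1, 2.25-fold, 1.41–3.598) higher. Of MHC class II genes 7 of 11 were lower (median log2 ratio −0.28, percentile 0.295), for example H2-Eb1 (5786 against 7637, 1.32-fold, 1.29–1.35). Of inflammatory genes 9 of 16 were higher (median log2 ratio 0.24, percentile 98.8, negative at a finer clustering), Saa3 (70.7 against 5.33, 13.3-fold, 8.23–22.4) against Ccl8 (26.2 against 170.4, 6.51-fold, 4.84–8.96). Endothelial cells, numerous enough in WT alone, had 24 of 25 IFN-γ response genes higher (median log2 ratio 0.96, percentile 100), with Cxcl9 (155 against 4.04, 38.3-fold, 10.4–319), Igtp (176 against 16.2, 10.9-fold, 5.41–25.6) and Gbp4 (647 against 164, 3.95-fold, 3.13–5.04). So were 8 of 12 inflammatory genes (median log2 ratio 0.71, percentile 100), with Saa3 (128 against 0, at least 21.1-fold). But 1 cell held 125 of 133 Saa3 UMIs, and with the richest cell of each gene left out 5 members remained, with a median of −0.12. Of dissociation stress genes 17 of 19 were lower in them (median log2 ratio −0.66, percentile 0). That list had medians for WT and Cd226-/- of 0.59 and 0.24 (percentiles 100 and 99.9) in neutrophils, 0.086 and −0.39 (percentiles 21.2 and 0.0300) in fibroblasts and 0.17 and −0.096 (percentiles 78.7 and 3.45) in phagocytes. It turned negative in WT fibroblasts and just positive in Cd226-/- phagocytes under trimmed-mean scaling, and negative in Cd226-/- neutrophils with each library clustered on its own. Collagen and matrix genes were at 2.23 and 0.70 in neutrophils. The lower genes of endothelial cells were collagens, Col1a2 (577 against 10404, 18.0-fold, 16.6–19.7), Col1a1 (493 against 8724, 17.7-fold, 16.1–19.4) and Col3a1 (515 against 4166, 8.09-fold, 7.35–8.91), in a naive library of 97.0% fibroblasts among non-immune cells. Trimmed-mean scaling moves the neutrophil log2 ratios of Cd226-/- over naive by 0.28. Keratinocytes, with 24 cells in Cd226-/- and 60 in naive CD45- skin, were too few to compare.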

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

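2 lists had medians of opposite sign in the treated genotypes against the same naive cells, with each median outside the middle 95% of medians of random lists. Other lists had opposite signs with at least 1 median inside that range. Type 2 genes of lymphocytes had a median log2 ratio of −1.13 in WT and 1.04 in Cd226-/-, with 2 of 6 and 4 of 8 members higher. Cell cycle genes of macrophages and monocytes had 0.17 in WT and −0.67 in Cd226-/-, with 14 of 24 and 3 of 24 higher. The opposite signs do not hold throughout. The type 2 median in WT was 0.39 at resolution 2.0 and 1.63 at a minimum of 200 UMIs, and 0.49 with the richest cell of each gene left out, and in Cd226-/- it was −0.078 with each library clustered on its own. Cell cycle medians of WT and Cd226-/- were 1.04 and 0.55 in macrophages alone and −0.16 and −0.10 in monocytes alone, the latter from 3 and 5 members, and in WT −0.73 at resolution 2.0 and −1.53 with each library clustered on its own. Neither difference between the genotypes was tested, since each is 1 library, and both naive values come from a library labelled as a pool of the genotypes.

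Cells that a sort should have removed were present and, but for the reading of Cd226 and of the fibroblast background, were not used: 110 of 10597 cells of the naive CD45- library fell into immune classes (1.04%), and 171 of 3494 of the naive CD45+ library into non-immune classes (4.89%). A sort with no leftover would have given none.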

How the results depend on the processing

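Monocytes and macrophages apart, the richest cell of each gene left out, the median of 100 thinning draws and the genes read over all immune cells were alternatives chosen after seeing the data; the rest were planned. No paired analysis was possible because each group is 1 library. Given here are the class shares and main lists (IFN-γ, and inflammatory between genotypes) that moved out of their interval, and every value that turned in sign where the main interval excluded 0. For a list this interval is the median with, on either side, the half-width of the counting interval of its middle gene or genes. The main value is in parentheses, shares in percentage points and lists and genes in log2; the cause was not tested. Moves of 182 values of other lists and 344 of named genes are counted and not listed. With the looser cell filter, in WT against naive neutrophil share −4.42 (−7.67), lymphocyte inflammatory −0.21 (0.44), and in Cd226-/- against naive neutrophil share −4.21 (−7.82), and in Cd226-/- against WT neutrophil inflammatory −0.032 (−0.16). With doublets kept, in Cd226-/- against WT fibroblast IFN-γ −0.46 (−0.44), Langerhans inflammatory −0.26 (−0.49), neutrophil Saa3 0.11 (−1.85). At resolution 2.0, in WT against naive monocyte share 7.60 (18.0), macrophage share −29.1 (−39.4), fibroblast share −15.8 (−17.3), lymphocyte type 2 0.39 (−1.13), phagocyte type 17 −0.44 (2.48), and in Cd226-/- against naive monocyte share 18.6 (29.0), macrophage share −34.7 (−45.9), fibroblast share −8.48 (−11.0), phagocyte cytotoxic and type 1 effector −0.48 (0.97), dendritic inflammatory −0.023 (0.24), and in Cd226-/- against WT lymphocyte cell cycle 0.60 (−0.27), phagocyte cytotoxic and type 1 effector 0.037 (−1.29), phagocyte regulatory T cell 0.058 (−0.81). With each library clustered on its own, in Cd226-/- against WT macrophage share −9.30 (−6.53), lymphocyte share −5.78 (−3.20), Langerhans share −0.0333 (−3.73), neutrophil share −2.75 (−0.155), lymphocyte inflammatory 1.16 (−0.085), Langerhans inflammatory 0.24 (−0.49), Langerhans dissociation stress 0.024 (−0.28), Langerhans keratinocyte wound and hyperproliferation 0.97 (−0.78), neutrophil inflammatory 0.11 (−0.16), Langerhans Ccl2 0.78 (−1.32), Langerhans H2-Aa −0.0031 (0.14), lymphocyte Bst2 −0.15 (0.47), lymphocyte Cd163l1 −0.13 (0.93), phagocyte Ccl1 −1.88 (2.19), and in WT against naive monocyte share 15.9 (18.0), macrophage share −44.0 (−39.4), fibroblast share −15.7 (−17.3), lymphocyte inflammatory −0.091 (0.44), phagocyte MHC-II −0.11 (0.062), phagocyte alternative 0.011 (−0.15), lymphocyte Irf8 −0.48 (0.98), phagocyte Cd74 −0.0063 (0.063), and in Cd226-/- against naive monocyte share 25.9 (29.0), macrophage share −53.3 (−45.9), lymphocyte share 5.95 (10.3), fibroblast share −9.16 (−11.0), lymphocyte type 2 −0.078 (1.04), neutrophil dissociation stress −0.21 (0.24), lymphocyte Irf8 −0.0066 (1.77). Under trimmed-mean scaling, in Cd226-/- against WT fibroblast IFN-γ −0.48 (−0.44), neutrophil inflammatory 0.016 (−0.16), neutrophil dissociation stress 0.065 (−0.11), and in WT against naive fibroblast IFN-γ 0.64 (0.86), fibroblast type I −0.015 (0.21), fibroblast dissociation stress −0.14 (0.086), and in Cd226-/- against naive fibroblast IFN-γ 0.13 (0.36), phagocyte dissociation stress 0.0034 (−0.096). With cells weighted equally, in Cd226-/- against WT fibroblast IFN-γ −0.42 (−0.44), phagocyte regulatory T cell 0.14 (−0.81), neutrophil inflammatory −0.12 (−0.16), and in WT against naive fibroblast dissociation stress −0.094 (0.086), lymphocyte cell cycle 0.075 (−0.37). At a minimum of 1 UMI, in WT against naive fibroblast IFN-γ 0.96 (0.86). At a minimum of 200 UMIs, in Cd226-/- against WT fibroblast inflammatory 0.44 (0.60), phagocyte inflammatory 0.18 (0.054), phagocyte cytotoxic and type 1 effector 0.011 (−1.29), Langerhans inflammatory −0.28 (−0.49), neutrophil inflammatory −0.050 (−0.16), and in WT against naive lymphocyte type 17 0.84 (−0.52), lymphocyte type 2 1.63 (−1.13), phagocyte type 17 −0.15 (2.48), and in Cd226-/- against naive fibroblast IFN-γ 0.20 (0.36), phagocyte cytotoxic and type 1 effector −0.30 (0.97), dendritic IFN-γ −0.025 (−0.13). In monocytes alone, in Cd226-/- against WT cell cycle 0.38 (−0.82), cytotoxic and type 1 effector 0.014 (−1.29), and in WT against naive IFN-γ 0.70 (−0.17), inflammatory −0.076 (0.99), alternative 0.47 (−0.15), classical −0.037 (1.01), cytotoxic and type 1 effector −0.060 (1.83), and in Cd226-/- against naive IFN-γ 0.37 (−0.65), MHC-II 0.033 (−0.82), alternative 0.40 (−0.34), dissociation stress 0.10 (−0.096). In macrophages alone, in WT against naive IFN-γ 0.084 (−0.17), alternative 0.13 (−0.15), and in Cd226-/- against naive MHC-II 0.029 (−0.82), alternative 0.27 (−0.34), cell cycle 0.55 (−0.67).

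Of 137 alternative values for class shares 118 stayed within the interval and 135 kept their direction; of 45 for effector genes all stayed within it and 42 kept direction, and of 9 for Cd226 all did both. The effector shares were varied in thinning alone, and Cd226 in cell filter, doublets and thinning draws alone. Neither was taken under another clustering, so these counts cannot show whether they depend on it. Of 167 values for the main lists 145 did and 156 kept direction, of 850 for other lists 628 and 785, and of 1628 for named genes 1275 and 1607. With each library clustered on its own, WT dendritic cells and naive CD45+ Langerhans and dendritic cells stayed unnamed, so that no value exists there. Depth limits genes near 50 UMIs, for which intervals span several-fold.

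With the richest cell of each gene left out of each library, 10 of the 261 gene ratios given whose interval excluded equality no longer had such an interval: in Cd226-/- against WT Langerhans Igfbp2, Langerhans Sostdc1, fibroblast Jchain, lymphocyte Cxcl9, neutrophil Coch, neutrophil Saa3, phagocyte Ccl1, and in Cd226-/- against naive neutrophil Coch, phagocyte Ccl1, and in WT against naive endothelial Saa3. Penk in Langerhans cells turned to −2.94 (3.70). These list medians turned: in Cd226-/- against WT lymphocyte inflammatory 0.052 (−0.085), phagocyte classical 0.061 (−0.14), and in WT against naive lymphocyte type 2 0.49 (−1.13), monocyte inflammatory 0.19 (−0.076), macrophage alternative −0.0027 (0.13), endothelial inflammatory −0.12 (0.71), and in Cd226-/- against naive phagocyte classical −0.29 (0.072), neutrophil type 17 −2.56 (6.16), monocyte classical 0.23 (−0.030), macrophage MHC-II −0.074 (0.029). The type 17 list of neutrophils had no member left in Cd226-/- against WT. Folds can be larger without that cell too, as where it was a naive one.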

Other observations

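The lymphocytes of the 2 treated libraries lean to different effector genes. WT held 635 Ifng and 174 Il13 UMIs, Cd226-/- 257 Ifng and 810 Il13 UMIs, and Areg went with Il13. In fibroblasts of Cd226-/- inflammatory genes such as Saa3 and Csf3 were higher and IFN-γ response genes such as Cxcl9 and Gbp4 lower. Type I interferon genes were lower in treated than in naive neutrophils, phagocytes and lymphocytes of both genotypes, with Rsad2 lower in each.

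A group of non-immune cells that took no class name was 8.20% (7.47 to 8.99) of non-immune cells in WT, 7.33% (6.46 to 8.28) in Cd226-/- and 0.114% (0.0591 to 0.1998) in naive CD45- skin. A second was 1.45%, 2.55% and 0%. Staining treated and naive skin for the Wnt regulator Sostdc1, high in the first group, would show where these cells sit.

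In the 3 patterns weighed next, the tests on free RNA from fibroblasts and lymphocytes were set before their results were seen and all other tests after them. IFN-γ response genes were lower in macrophages and monocytes of Cd226-/-. Free RNA from fibroblasts is argued against as the whole cause: after its subtraction the list median was −0.42, against −0.44 before. The half-width of the counting interval of the list's middle genes is 0.34. Free RNA from lymphocytes is argued against in the same way, with a median of −0.42 after subtraction. A larger share of monocytes is argued against as well, though narrowly: monocytes, the part of the class nearer to 0, had −0.29 with a half-width of 0.26. In lymphocytes and Langerhans cells the median lies within this half-width (0.37 and 0.28), although at percentiles 0 and 0.49 of random lists. These classes leave the pattern open. Genotype may be the cause of the −0.44, and it cannot be told apart from other differences between 2 pools of mice or their handling (dissociation stress genes were lower too, with a median of −0.19), because each genotype is 1 library; IFN-γ staining and repeat libraries per mouse would test it.

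Ifng was lower in lymphocytes of Cd226-/-, with a log2 ratio of −1.65. A different mix of sub-clusters is argued against as the whole cause, as within sub-cluster 0, which held most of the WT Ifng UMIs, the ratio was −0.64 (−0.92 to −0.37). The mix may still carry the larger part, since Cd226-/- levels weighted by the WT mix gave −0.67, although the sub-clusters were drawn on variable genes that can include Ifng. Genotype, acting on which cells are there or on what each makes, cannot be told apart from mouse or library, because each genotype is 1 library. Restimulated, sorted subsets from several mice per genotype would separate these.

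Glo1 was higher in fibroblasts, lymphocytes, phagocytes and Langerhans cells of Cd226-/-, in fibroblasts by 1.13 (log2). Scaling by total UMIs is argued against, as 28 genes within 1.5 Mb on either side of chromosome 17:30215524-30877365 (GRCm38) had a median of 0.045 in the same cells. A difference between the mice in the segment that holds Glo1 is a candidate explanation, as the neighbour nearer to 0 still had 0.79 there, though in Langerhans cells Btbd9, 1.22-fold (0.890 to 1.67), had an interval that includes equality. In naive skin, however, Glo1 was 62.6 CPM in fibroblasts and 147 in lymphocytes, though both libraries are labelled as equal pools. Genotype at Cd226 cannot be told apart from it, because each genotype is 1 library, and genotyping the segment would test it.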
